A study of Mus musculus with 21 samples.

How the data were processed

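Fibroblasts were sorted from lungs of female C57BL/6 mice carrying a Col1a2 promoter transgene for green fluorescent protein, per the labels' protocols. Mice were left untreated or received bleomycin or silica by oropharyngeal aspiration, and lungs were taken at day 7, 14 or 63. Lungs were digested with collagenase, Dispase and DNase, erythrocytes and silica were removed on Percoll, cells positive for CD45, CD31, EpCAM, CD146 or Ter119 were depleted, and fluorescent cells were sorted at 10000 cells per sample. RNA was captured on oligo(dT) beads and amplified, and tags from the 3′ ends of transcripts were sequenced on an Ion Proton instrument (3′SAGE-seq). The deposited files held counts of reads per gene symbol, 1 file per library, with no normalization. The submitters' processing notes named Bowtie2 2.2.5 and mm10, and stated no annotation, counting program, filter or strand setting. Genes that share sequence with a near-identical copy, and genes that overlap on opposite strands, are therefore uncertain. Of the deposited symbols, 17830 (76.8%) matched a gene name of GENCODE vM21, and symbols were used as deposited.

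Total counts per library ran from 2080636 to 4477283. Libraries were grouped by the deposited labels into untreated, BLM day 7, 14 and 63 and SiO2 day 7, 14 and 63, with 3 libraries each. Genes with low counts were removed with edgeR's filterByExpr by group, which left 11669, and libraries were scaled by TMM. A single quasi-likelihood model with the 7 groups as a factor and 14 residual degrees of freedom was fitted in edgeR 4.0.16 (R 4.3.3), with a biological coefficient of variation of 12.0%. The 12 contrasts were each treated group against untreated, SiO2 against BLM at each day, day 63 against day 14 in each model, and the interaction of model and time, which is the change from day 14 to day 63 in silica minus that in BLM. P-values were adjusted over the 11669 genes of each contrast by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Standard errors of log2 fold changes came from the same model. All adjusted p for single genes are from this quasi-likelihood test.

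The 28 gene lists covered fibrillar collagen and cross-linking, matrix glycoprotein and proteoglycan, basement membrane, matrix proteases and inhibitors, contractile, TGF-beta response, Wnt signalling, alveolar and lipid-storing fibroblast, adventitial fibroblast, LXR targets, fatty acid synthesis, cholesterol synthesis, proliferation, p53 and senescence, chemokine and cytokine, interferon response, complement, unfolded protein response and secretion, NRF2 and oxidative stress, and glycolysis and hypoxia. They also covered markers of myeloid cells, lymphocytes, epithelium, endothelium, pericytes and smooth muscle, mesothelium and erythroid cells, and dissociation and immediate-early genes. Lists with at least 3 tested members, 27 in each comparison, were tested with camera (limma 3.58.1) with an estimated correlation, adjusted over the lists of a comparison. Of 324 list tests, 64 passed, and all of these were among the 170 that passed with the correlation preset at 0.01. Members were counted at an adjusted p under 0.05 over all tested genes and adjusted over the list alone.

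The genes named in the text followed a rule. In each comparison they were, of the called genes with libraries that did not overlap between the groups and a mean of at least 10 CPM in the higher group, the 6 with the largest and the 6 with the smallest log2 fold change. Libraries of groups of 3 fail to overlap by chance in 10% of genes, and the interaction carried no such condition. They were also up to 4 tested members of each list with the smallest adjusted p. Named in any comparison were Col1a1, Col1a2, Col3a1, Fn1, Eln, Lox, Acta2, Tagln, Tnc, Postn, Cthrc1, Spp1, Timp1, Tcf21, Npnt, Inmt, Srebf1, Abca1, Mki67, Top2a and Cdkn1a. The contrasts, lists, rule and alternatives were fixed before the data were examined. From the genes the rule allowed, those described in the text were picked after their values were seen, and members that lost their call without 1 library were mostly left out.

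A gene listed at 0 in every library of a group was given as a lower bound of the fold, against a floor of 3 counts over that group, and a gene with 1 to 3 counts in a group as a ratio with an exact 95% counting interval. Early genes were those called against untreated at day 7 or 14, in the same direction where called at both, and the share called again at day 63 in that direction was counted. The comparisons that share untreated libraries were set beside 20 simulations of unchanged groups against the same controls.

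The steps were tested on simulated data. Counts for the 11669 genes were drawn for all 21 libraries from each gene's mean over all libraries and from the library sizes. With 200 genes changed by known folds, edgeR recovered 26.6% of those changed 1.5-fold, 51.5% of those changed 2-fold and 90.8% of those changed 4-fold, and 5.98% of its calls were false. Where no gene was changed, with means of SiO2 day 63 and untreated, edgeR, DESeq2 and limma-voom made 0 calls.

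The alternatives were DESeq2's size factors and upper quartile factors in the same test, no filter on low counts, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit on the compared groups alone, a minimum of 2-fold, each library left out in turn, and, for lists, a preset correlation and the directional test of fry. Nothing deposited was left out.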

Results

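Messenger RNA was measured in fibroblasts sorted from the lungs of Col1a2-GFP mice, a transgenic line in which cells that express the collagen gene Col1a2 carry a green fluorescent protein. Lung fibrosis was started by aspiration of bleomycin (BLM) at 2 mg/kg, which the series describes as the reversible model, or of silica (SiO2) at 400 mg/kg, which it describes as the progressive model. The 21 libraries formed 7 groups of 3: untreated mice, and mice at day 7, 14 and 63 of each model. Total counts per library ran from 2080636 (untreated replicate 3) to 4477283 (SiO2 day 63 replicate 3) with a median of 3774431, and 14963 to 16224 gene symbols had a count. Of the deposited symbols, 11669 passed the filter on low counts and carried 99.68% of all counts, and 11535 did not pass. The 10 most abundant genes took 13.3% to 16.8% of the counts of a library. Ribosomal RNA entries took 0.174% to 0.219% of the counts in the untreated libraries and 0.290% to 0.493% in the 18 treated ones (two-sided exact permutation test, p = 0.00075, the smallest that its 1330 groupings can give). The labels gave no sequencing batch or date, so no value could be recomputed within a batch. The replicate numbers did not say whether libraries came from separate mice, and the p-values therefore measured only the spread between these samples.

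**Figure D1:**
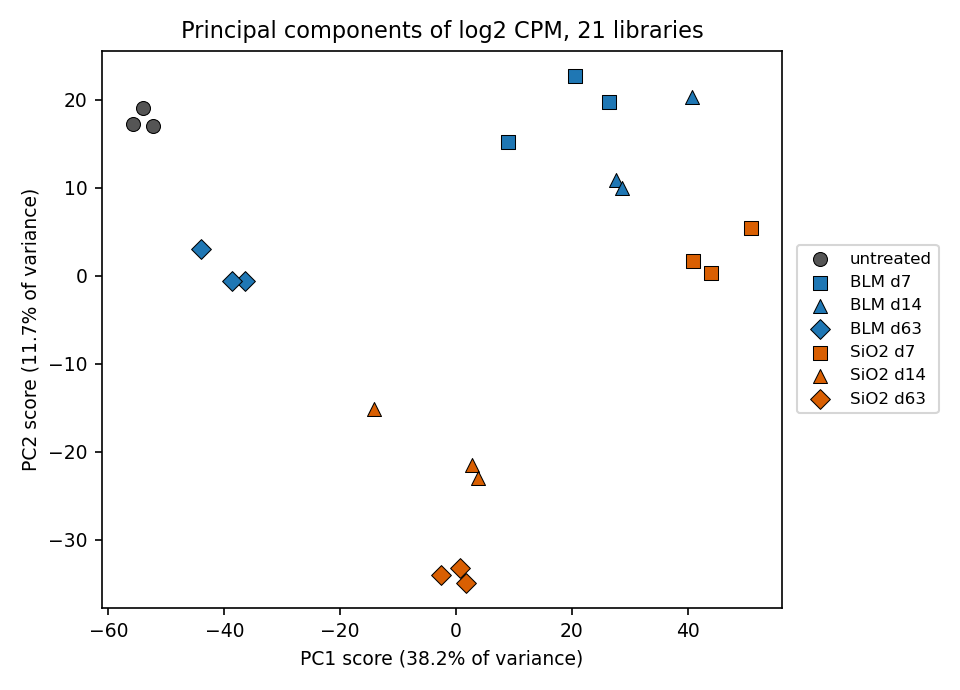
Positions of the 21 libraries on the first 2 principal components of log2 CPM (counts scaled to library size) over the tested genes, 1 point per library, coloured by group. The axes give component scores, and the components held 38.2% and 11.7% of the variance. The untreated libraries sat at the low end of component 1, next to those of BLM day 63.

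Values written after a gene symbol are log2 fold changes ± SE, with n = 3 libraries per group, and values in CPM are means ± SD of 3 libraries. Rose, fell, higher and lower mark genes that passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. For a list of genes fixed beforehand, the count of members that passed among all tested genes is followed by the count adjusted over the list alone. The adjusted p after it is that of camera, which compares the list with all other genes and was run with an estimated correlation. Of the 28 lists, the erythroid markers had 0 members tested. In the mm10 build (GENCODE vM21) the genes plotted over time lay at chromosome 11 94936224 to 94953042 (Col1a1), chromosome 3 54361109 to 54391037 (Postn), chromosome 5 104435118 to 104441050 (Spp1), chromosome X 20870166 to 20874735 (Timp1), chromosome 11 98992943 to 99024189 (Top2a) and chromosome 6 55170626 to 55175043 (Inmt). The tags carried no molecular identifiers and came from amplified RNA, so counting intervals and floors cover counting error only.

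**Figure D2:**
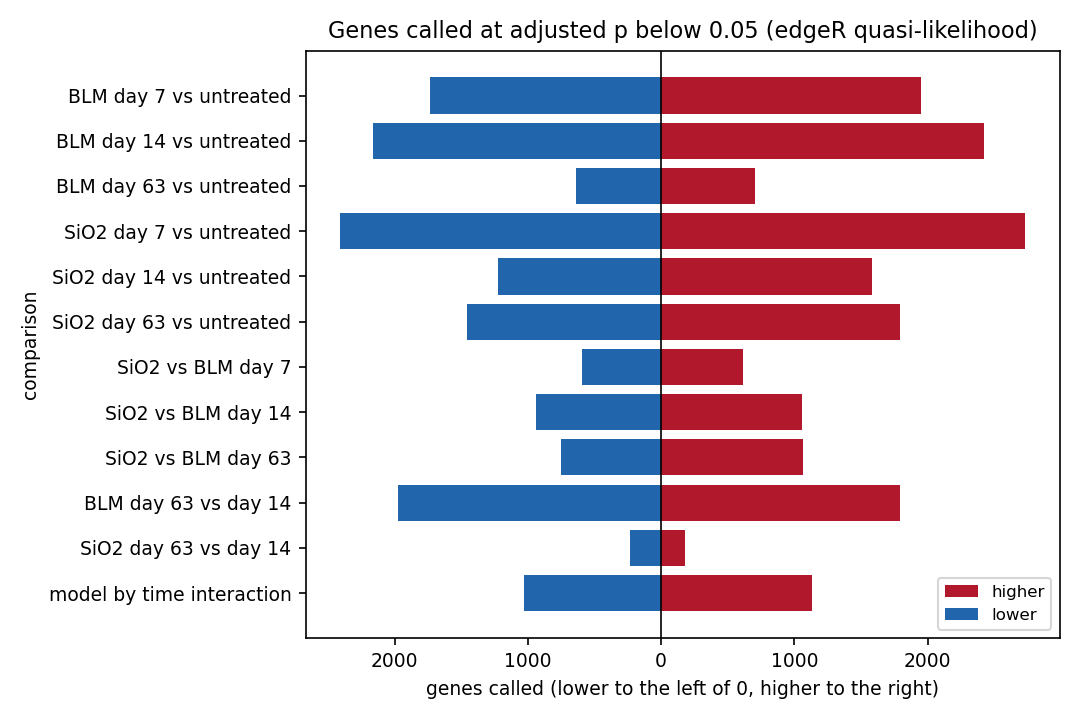
Number of genes with an adjusted p under 0.05 in each of the 12 comparisons, with genes higher in the first group drawn to the right of 0 and genes lower drawn to the left. The counts ran from 411 (SiO2 day 63 against day 14) to 5142 (SiO2 day 7 against untreated).

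The comparison of BLM day 7 with untreated mice addressed the start of fibrosis in the reversible model. Osteopontin, a secreted matrix phosphoprotein encoded by Spp1, went from 0.909 ± 0.143 CPM in untreated lungs to 877 ± 221 CPM, and the protease inhibitor Timp1 from 14.2 ± 2.30 to 164 ± 16.4 CPM. Of the proliferation genes, 27 of 27 rose (27 adjusted over the list alone, adjusted p = 0.0389). The topoisomerase Top2a (4.40 ± 0.37), Mki67 (3.53 ± 0.43) and Nusap1 (3.27 ± 0.24) were among them, on the log2 scale. Matrix glycoprotein and proteoglycan genes followed, as 17 of 23 rose and 4 fell (17 and 4 adjusted over the list alone, adjusted p = 0.0138). Those that rose included Spp1 (9.87 ± 0.56), tenascin Tnc (3.96 ± 0.21), periostin Postn (2.66 ± 0.41) and fibronectin Fn1 (1.68 ± 0.16). In the fibrillar collagen and cross-linking list 16 of 25 rose and 2 fell (16 and 2 adjusted over the list alone, adjusted p = 0.0405), with Col1a1 (1.48 ± 0.13), Col3a1 (1.42 ± 0.12) and Col5a2 (2.09 ± 0.16) among those that rose. Contractile genes showed smooth muscle actin Acta2 (2.73 ± 0.25) and nonmuscle myosin Myh9 (1.89 ± 0.15), and 12 of 20 rose (13 adjusted over the list alone, adjusted p = 0.0883 with an estimated correlation). Of the alveolar and lipid-storing fibroblast genes, 1 of 19 rose and 15 fell (1 and 15 adjusted over the list alone, adjusted p = 0.0449). Integrin Itga8 (-1.12 ± 0.11), nephronectin Npnt (-1.47 ± 0.14), the transcription factor Tcf21 (-1.30 ± 0.14) and the methyltransferase Inmt (-2.30 ± 0.24) fell, while lipoprotein lipase Lpl (2.65 ± 0.20) rose. In the p53 and senescence list 8 of 19 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.0716 with an estimated correlation), with the cycle inhibitor Cdkn1a (0.82 ± 0.15) and Eda2r (1.70 ± 0.19) higher. The transcription factor Tfap2a was at least 46.1-fold higher, Ptprn at least 45.5-fold higher and the adhesion molecule Chl1 224-fold higher (95% counting interval 39.8 to 8877), and the imprinted RNA H19 (5.94 ± 0.53) rose. The insulin-like growth factor binding protein Igfbp3 (-3.75 ± 0.22), the acetylcholinesterase anchor Colq (-4.63 ± 0.58) and the receptor Gpr111 (-3.20 ± 0.40) were among the largest falls. Interferon-response genes counted 13 of 26 higher and 1 lower (15 and 1 adjusted over the list alone, adjusted p = 0.471 with an estimated correlation), with Isg15 (1.86 ± 0.27), and summed to 3128 ± 1248 CPM against 2256 ± 194 CPM untreated. That rise of 872 CPM was 153 CPM without BLM day 7 replicate 1, with 9 members higher and 4 lower. Markers of other cells also moved. Epithelial markers counted 2 of 5 higher (2 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation), with the surfactant gene Sftpb (2.88 ± 0.38) at 9.76 ± 0.628 CPM. Myeloid markers counted 5 of 8 higher (5 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation), with Tyrobp (2.00 ± 0.32) at 16.2 ± 4.72 CPM. Lymphocyte markers counted 1 of 3 higher (1 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation), with Ccl5 (3.35 ± 0.34). In total 3685 genes passed, 1951 higher (52.9%, or 47.0% under upper quartile scaling) and 1734 lower. The largest adjusted p among genes named as changed was 5.61e-05. The list tests ended without untreated replicate 1 (0.0536 for proliferation, fibrillar collagen and alveolar genes) and without untreated replicate 3 (0.0514 for fibrillar collagen and alveolar genes). The alveolar test also ended without BLM day 7 replicate 2 or 3 (0.0598 and 0.0556).

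At BLM day 14 against untreated mice, Col1a1 stood at 3562 ± 345 CPM against 689 ± 27.4 CPM and osteopontin at 2086 ± 639 CPM. Of the fibrillar collagen and cross-linking genes, 19 of 25 rose and 2 fell (19 and 3 adjusted over the list alone, adjusted p = 0.00352). Collagens Col1a1 (2.37 ± 0.14), Col1a2 (2.01 ± 0.10) and Col5a2 (3.05 ± 0.16) and the cross-linking enzyme Lox (1.55 ± 0.15) were higher on the log2 scale. Matrix glycoprotein and proteoglycan genes counted 18 of 23 higher and 4 lower (19 and 4 adjusted over the list alone, adjusted p = 0.000292). Osteopontin Spp1 (11.12 ± 0.55), Postn (4.95 ± 0.34), Tnc (4.12 ± 0.21), Fn1 (2.95 ± 0.17), elastin Eln (2.32 ± 0.17) and thrombospondin Thbs2 (3.99 ± 0.21) rose. Thrombospondin Thbs4 was 388-fold higher (95% counting interval 107 to 3206), the secreted glycoprotein Cthrc1 403-fold higher (95% counting interval 72.0 to 15969) and Tfap2a at least 122-fold higher. In the list of matrix proteases and inhibitors 14 of 21 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 0.0130), with Timp1 (3.32 ± 0.17) and the metalloprotease Adam12 (4.68 ± 0.38). Basement membrane genes counted 8 of 16 higher and 3 lower (10 and 3 adjusted over the list alone, adjusted p = 0.0560 with an estimated correlation), with collagen Col4a1 (2.49 ± 0.16) higher and laminin Lama4 (-1.02 ± 0.11) lower. The TGF-beta response list counted 12 of 19 higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 0.0560 with an estimated correlation), with the binding protein Ltbp2 (3.70 ± 0.23) higher. Contractile Acta2 (3.14 ± 0.25) and Tagln (1.67 ± 0.24) and the cycle gene Top2a (3.37 ± 0.38) rose. Alveolar genes G0s2 (-3.06 ± 0.21) and Inmt (-3.18 ± 0.25) fell. So did the amino acid transporter Slc7a10 (-5.12 ± 0.56) and periplakin Ppl (-4.09 ± 0.45). Adventitial genes counted 3 of 18 higher and 9 lower (3 and 10 adjusted over the list alone, adjusted p = 0.244 with an estimated correlation), with Pcolce2 (-3.11 ± 0.17) and gelsolin Gsn (-2.72 ± 0.17) lower. Mesothelial markers counted 4 of 10 lower (4 adjusted over the list alone, adjusted p = 0.809 with an estimated correlation). Dissociation and immediate-early genes counted 3 of 20 higher and 11 lower (3 and 13 adjusted over the list alone, adjusted p = 0.435 with an estimated correlation). Interferon-response genes counted 11 of 26 lower (11 adjusted over the list alone, adjusted p = 0.477 with an estimated correlation), among them Stat2 (-1.38 ± 0.18), Gbp3 (-1.94 ± 0.24) and Ifit2 (-1.14 ± 0.21), although Gbp and Ifit genes have near-identical copies. They summed to 1469.9 ± 194 CPM against 2256 ± 194 CPM untreated. Endothelial markers counted 2 of 7 higher and 2 lower (2 and 2 adjusted over the list alone, adjusted p = 0.998 with an estimated correlation), with a median log2 change of -0.25 and a mean of 0.20, and Plvap (3.68 ± 0.40) rose. In total 4585 genes passed, 2421 higher (52.8%, or 45.7% under upper quartile scaling) and 2164 lower. Among genes named as changed the largest adjusted p was 7.45e-05.

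By BLM day 63, Postn stood at 3.26 ± 0.239 CPM and Inmt at 1323 ± 46.2 CPM, against 2.73 ± 0.351 and 1285 ± 64.0 CPM in untreated lungs. The differences did not pass for Col1a1 (-0.29 ± 0.13), Fn1 (0.24 ± 0.16), Postn (0.21 ± 0.54), Timp1 (0.35 ± 0.20) or Inmt (0.04 ± 0.23) on the log2 scale, with adjusted p of 0.181, 0.378, 0.865, 0.277 and 0.939. Still higher than untreated were Tnc (1.91 ± 0.22), Ltbp2 (2.19 ± 0.23), thrombospondin Thbs1 (1.08 ± 0.13), the collagens Col28a1 (4.51 ± 0.36) and Col12a1 (1.89 ± 0.26) and the prolyl hydroxylase P4ha3 (1.39 ± 0.24). The Wnt regulators Sfrp1 (1.70 ± 0.17) and Dkk3 (0.83 ± 0.12) and Lpl (2.04 ± 0.20) were also higher. So were the ion channel Piezo2 (3.19 ± 0.31), the growth factors Gdnf (3.16 ± 0.37) and Gdf6 (3.11 ± 0.32), Tmem178 (3.39 ± 0.50) and the contractile genes Myh9 (0.95 ± 0.14) and Des (1.39 ± 0.28). Among matrix glycoprotein and proteoglycan genes 9 of 23 rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 0.221 with an estimated correlation), and in the TGF-beta response list 8 of 19 rose (9 adjusted over the list alone, adjusted p = 0.221 with an estimated correlation). Mesothelial markers counted 6 of 10 lower (8 adjusted over the list alone, adjusted p = 0.221 with an estimated correlation), with Msln (-1.40 ± 0.28) and Krt19 (-1.27 ± 0.27) lower. Interferon-response genes counted 0 of 26 higher and 8 lower (1 and 14 adjusted over the list alone, adjusted p = 0.409 with an estimated correlation), with Stat2 (-1.07 ± 0.17) and Zbp1 (-1.60 ± 0.34) lower. Adventitial genes counted 2 of 18 higher and 5 lower (3 and 6 adjusted over the list alone, adjusted p = 0.409 with an estimated correlation), with Serpinf1 (-1.49 ± 0.17) and Clec3b (-1.14 ± 0.18) lower. The cross-linking enzyme Lox (-0.73 ± 0.15), Mfap4 (-1.19 ± 0.14), Npnt (-0.77 ± 0.13), palmdelphin Palmd (-3.08 ± 0.30), the transcription factor Zbtb16 (-2.15 ± 0.40) and the chemokine Cxcl5 (-2.84 ± 0.52) were lower, and the secreted protein Wfdc10 was at least 73.0-fold lower. Of the 27 proliferation genes tested, 0 passed in edgeR, DESeq2 or limma-voom, and 4 had an unadjusted edgeR p under 0.05 (list test adjusted p = 0.607 with an estimated correlation). In total 1343 genes passed, 703 higher (52.3%, or 47.2% under upper quartile scaling and 49.0% under DESeq2's size factors) and 640 lower. The largest adjusted p among genes named as changed was 0.00174. The total was 795 without untreated replicate 1 and 814 without BLM day 63 replicate 3.

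SiO2 day 7 against untreated mice addressed the start of fibrosis in the progressive model. Col1a1 reached 4378 ± 335 CPM and the acute-phase gene Saa3 1437 ± 238 CPM, against 689 ± 27.4 and 38.8 ± 15.0 CPM in untreated lungs. Of the fibrillar collagen and cross-linking genes, 20 of 25 rose and 4 fell (20 and 5 adjusted over the list alone, adjusted p = 0.00514), with Col1a1 (2.67 ± 0.14), Col1a2 (2.01 ± 0.10) and Col12a1 (4.39 ± 0.24) higher on the log2 scale. Proliferation genes counted 27 of 27 higher (27 adjusted over the list alone, adjusted p = 0.0422), with Top2a (4.79 ± 0.36), Mki67 (3.73 ± 0.42) and Nusap1 (3.37 ± 0.24). Matrix glycoproteins Spp1 (10.31 ± 0.55), Thbs2 (5.17 ± 0.21), Postn (4.34 ± 0.35), Tnc (3.85 ± 0.21) and Fn1 (2.01 ± 0.16) and the contractile gene Acta2 (3.44 ± 0.25) rose. In the chemokine and cytokine list 18 of 25 rose and 3 fell (18 and 3 adjusted over the list alone, adjusted p = 0.0325), including Cxcl5 (4.14 ± 0.23), Cxcl12 (2.69 ± 0.16) and Saa3 (5.24 ± 0.40), although Saa genes have near-identical copies. Of the glycolysis and hypoxia genes 11 of 18 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 0.0209), with the lactate exporter Slc16a3 (4.53 ± 0.19) and the glucose transporter Slc2a1 (1.45 ± 0.10) higher. Targets of liver X receptors (LXR), which govern sterol export, counted 9 of 14 higher and 3 lower (9 and 3 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), with the phospholipid transfer protein Pltp (1.65 ± 0.21) higher. The bone morphogenetic protein antagonist Grem1 was at least 208-fold higher, Elfn1 at least 96.9-fold higher and laminin Lama1 at least 67.1-fold higher. Alveolar and lipid-storing fibroblast genes counted 1 of 19 higher and 17 lower (1 and 17 adjusted over the list alone, adjusted p = 0.0120), with Npnt (-2.57 ± 0.14), Limch1 (-1.60 ± 0.09), Itga8 (-1.80 ± 0.11) and Inmt (-3.55 ± 0.25) lower. Adventitial genes counted 3 of 18 higher and 12 lower (3 and 12 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation), with Pcolce2 (-3.29 ± 0.17) and Gsn (-2.94 ± 0.17) lower. Mesothelial markers counted 7 of 10 lower (8 adjusted over the list alone, adjusted p = 0.214 with an estimated correlation), with Upk1b (-2.15 ± 0.12) and Krt19 (-1.50 ± 0.27) lower. Dissociation and immediate-early genes counted 3 of 20 higher and 14 lower (4 and 14 adjusted over the list alone, adjusted p = 0.214 with an estimated correlation), with Atf3 (-2.16 ± 0.19) and Egr1 (-1.10 ± 0.12) lower. The repressor Cbfa2t3 (-4.13 ± 0.31), Fam222a (-4.34 ± 0.35) and the glutathione transferase Gstm1 (-3.30 ± 0.27) fell. Pericyte and smooth muscle markers counted 5 of 8 higher (5 adjusted over the list alone, adjusted p = 0.0325), with Notch3 (3.35 ± 0.42) higher. Epithelial markers counted 3 of 5 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.426 with an estimated correlation), with Sftpb (2.73 ± 0.38) at 8.76 ± 2.07 CPM against 1.25 ± 0.289 CPM. Lymphocyte markers counted 1 of 3 higher and 0 lower (1 and 1 adjusted over the list alone, adjusted p = 0.515 with an estimated correlation), with a median log2 change of -1.45, a mean of 0.05 and an upward test, and Ccl5 (3.67 ± 0.33) rose from 4.08 ± 1.10 to 55.1 ± 22.5 CPM. In total 5142 genes passed, 2734 higher (53.2%, or 46.5% under upper quartile scaling) and 2408 lower. Among genes named as changed the largest adjusted p was 4.42e-05. The proliferation test gave 0.0604 and 0.0569 without untreated replicate 1 or 2, and the pericyte test 0.0520 with no filter on low counts.

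At SiO2 day 14 against untreated mice, complement genes together held 14484 ± 529.8 CPM against 7449.8 ± 152 CPM, and interferon-response genes 4358 ± 639 against 2256 ± 194 CPM. Of the complement genes, 11 of 13 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.0219). Members C3 (1.67 ± 0.13), C4b (1.35 ± 0.12) and Serping1 (0.85 ± 0.09) rose on the log2 scale. Chemokine and cytokine genes counted 18 of 25 higher (21 adjusted over the list alone, adjusted p = 0.00119), with Cxcl12 (2.42 ± 0.16), Cxcl5 (3.07 ± 0.25) and Saa3 (4.49 ± 0.39). Interferon-response genes counted 18 of 26 higher (20 adjusted over the list alone, adjusted p = 0.0959 with an estimated correlation), including Ifit3 (2.42 ± 0.29) and Usp18 (2.61 ± 0.34). Fibrillar collagen and cross-linking genes counted 17 of 25 higher and 2 lower (18 and 2 adjusted over the list alone, adjusted p = 0.00167). Collagens Col1a1 (1.74 ± 0.14), Col3a1 (1.67 ± 0.12) and Col5a2 (2.06 ± 0.16) stayed higher than untreated. Basement membrane genes counted 12 of 16 higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 0.00304), with Col4a1 (1.67 ± 0.15), Col4a2 (1.21 ± 0.10) and Agrn (1.23 ± 0.18). Glycoproteins Spp1 (6.49 ± 0.62), Ltbp2 (3.76 ± 0.23), Thbs2 (3.64 ± 0.22), Postn (3.46 ± 0.38) and Tnc (2.54 ± 0.21) and the proteases Ctsk (2.57 ± 0.27) and Mmp2 (0.96 ± 0.13) were higher. The TGF-beta response list counted 13 of 19 higher and 2 lower (13 and 2 adjusted over the list alone, adjusted p = 0.0383). LXR targets counted 5 of 14 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0244), with the cholesterol exporter Abca1 (1.32 ± 0.15) and Pltp (1.48 ± 0.21). Grem1 was at least 47.4-fold higher, the kinesin Kif26b 111-fold higher (95% counting interval 30.4 to 922) and Tfap2a at least 44.4-fold higher. The receptor Acvr2b (-2.03 ± 0.37), the potassium channel Kcna2 (-1.92 ± 0.23), Cbfa2t3 (-1.89 ± 0.25), Fam222a (-2.11 ± 0.27), Inmt (-1.40 ± 0.23), Npnt (-0.85 ± 0.13) and G0s2 (-1.60 ± 0.20) fell. Proliferation genes counted 2 of 27 higher (2 adjusted over the list alone, adjusted p = 0.616 with an estimated correlation), with Mki67 (0.85 ± 0.58) not passing (adjusted p = 0.313). Myeloid markers counted 6 of 8 higher (6 adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation) and summed to 93.5 ± 14.7 CPM against 34.6 ± 12.8 CPM, and Tyrobp (2.43 ± 0.30) rose. Pericyte and smooth muscle markers counted 4 of 8 higher (4 adjusted over the list alone, adjusted p = 0.0219) and summed to 256 ± 39.6 CPM against 122 ± 8.99 CPM, with Notch3 (2.32 ± 0.48). Mesothelial markers counted 3 of 10 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.831 with an estimated correlation). In total 2807 genes passed, 1583 higher (56.4%, or 44.8% under upper quartile scaling) and 1224 lower. The largest adjusted p among genes named as changed was 0.000451. The TGF-beta test gave 0.0530 and 0.0657 without untreated replicate 1 or SiO2 day 14 replicate 3, and the pericyte test 0.0772 with no filter on low counts.

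SiO2 day 63 against untreated mice addressed the late progressive model. Postn stood at 65.8 ± 7.58 CPM and Col1a1 at 1228 ± 24.3 CPM, against 2.73 ± 0.351 and 689 ± 27.4 CPM in untreated lungs. Of the matrix glycoprotein and proteoglycan genes, 16 of 23 rose and 4 fell (17 and 4 adjusted over the list alone, adjusted p = 0.00574). Among those that rose were Spp1 (7.46 ± 0.59), Postn (4.54 ± 0.35), Thbs2 (4.14 ± 0.21), Ltbp2 (4.12 ± 0.23) and Tnc (2.67 ± 0.21) on the log2 scale. Fibrillar collagen and cross-linking genes counted 14 of 25 higher and 2 lower (14 and 2 adjusted over the list alone, adjusted p = 0.0190), with Col3a1 (1.58 ± 0.12), Col1a1 (0.83 ± 0.13) and P4ha3 (2.89 ± 0.22). Contractile Acta2 (2.63 ± 0.25) was higher. Chemokine and cytokine genes counted 17 of 25 higher and 0 lower (18 and 1 adjusted over the list alone, adjusted p = 0.0113), with Cxcl12 (2.72 ± 0.16) and Cxcl5 (3.28 ± 0.24). Complement genes counted 9 of 13 higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.103 with an estimated correlation), with C3 (1.52 ± 0.13). LXR targets counted 6 of 14 higher (6 adjusted over the list alone, adjusted p = 0.0423), with Abca1 (1.36 ± 0.15), Pltp (2.24 ± 0.22) and Rgs16 (3.90 ± 0.32) higher. Cholesterol synthesis genes counted 9 of 24 higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.374 with an estimated correlation), with Sqle (1.53 ± 0.21) and Cyp51 (1.22 ± 0.16) higher. The sterol regulator Srebf1 gave 0.23 ± 0.22 (adjusted p = 0.468). Grem1 was at least 64.6-fold and Chl1 369-fold higher (95% counting interval 65.9 to 14614). Myeloid markers summed to 62.8 ± 7.33 CPM (34.6 ± 12.8 untreated), so the source of the lectin Clec4n (at least 33.4-fold higher) stays open. Alveolar and lipid-storing fibroblast genes counted 1 of 19 higher and 14 lower (1 and 15 adjusted over the list alone, adjusted p = 0.0492), with Npnt (-1.77 ± 0.14), Scn3a (-1.79 ± 0.19) and Inmt (-1.74 ± 0.23) lower. The mesothelial marker Upk1b (-1.26 ± 0.12), adventitial Pi16 (-1.58 ± 0.18), Fam222a (-3.50 ± 0.31) and the adrenergic receptor Adrb3 (-3.08 ± 0.38) were lower. Pericyte and smooth muscle markers counted 6 of 8 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0190), with Notch3 (3.46 ± 0.42). Lymphocyte markers counted 2 of 3 higher (2 adjusted over the list alone, adjusted p = 0.0556 with an estimated correlation), with Ccl5 (3.17 ± 0.34) at 38.9 ± 6.65 CPM. In total 3249 genes passed, 1789 higher (55.1%, or 45.7% under upper quartile scaling) and 1460 lower. Among genes named as changed the largest adjusted p was 1.19e-05. The alveolar test gave 0.0554 without untreated replicate 1 and 0.0558, 0.0520 and 0.0608 without SiO2 day 63 replicate 1, 2 and 3. The LXR test gave 0.0515 and 0.0558 without untreated replicate 1 and SiO2 day 63 replicate 1.

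**Figure D3:**
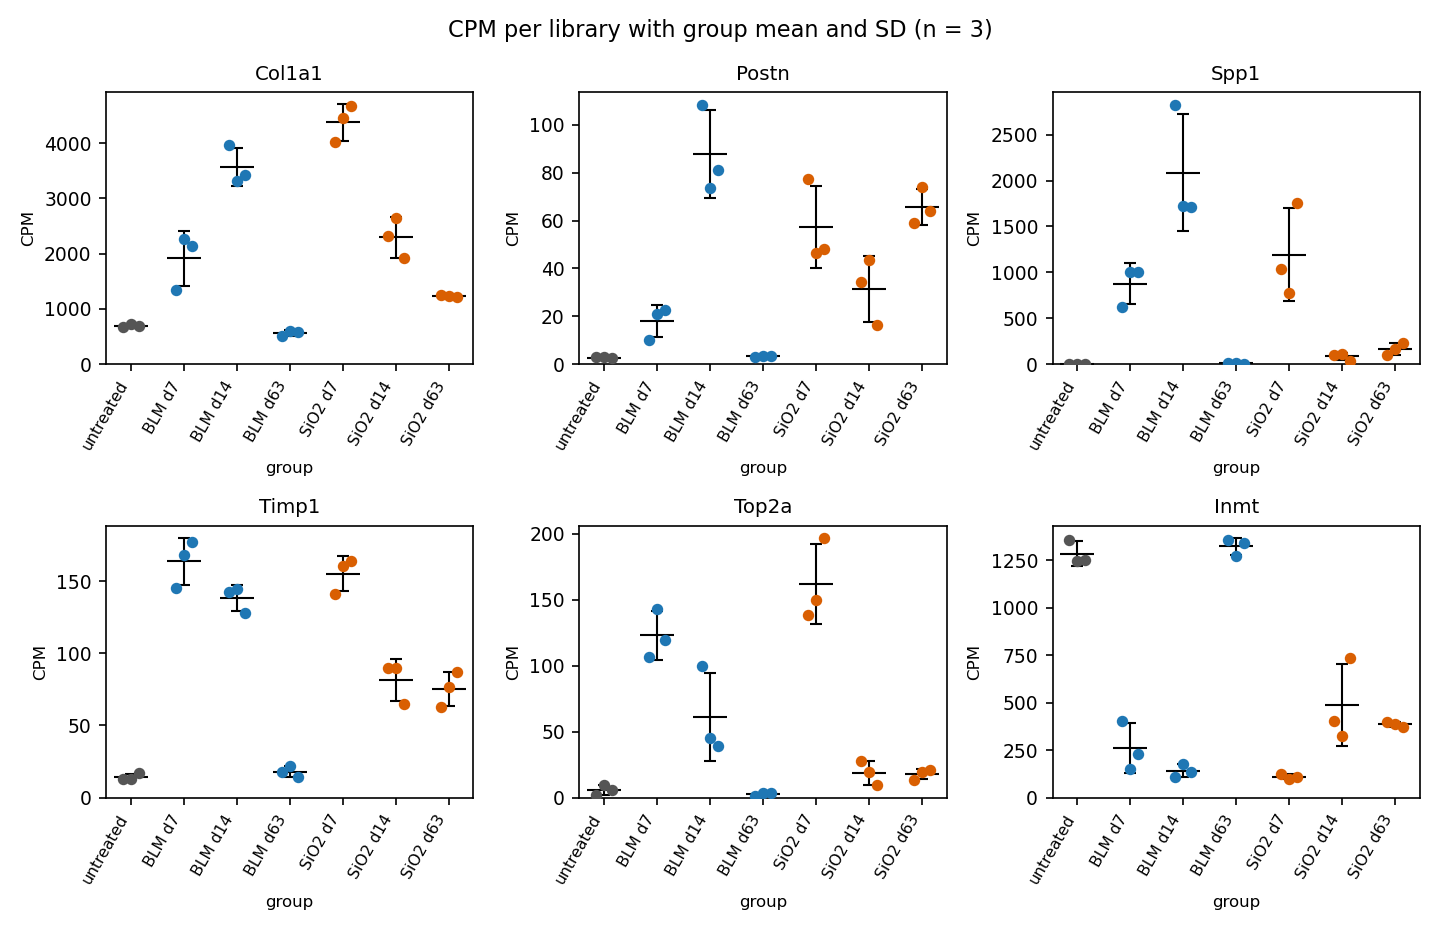
Expression of Col1a1, Postn, Spp1, Timp1, Top2a and Inmt in CPM in each of the 21 libraries by group, with points for libraries and a bar for the mean and SD of the 3 libraries of a group. Postn stood at 3.26 ± 0.239 CPM at BLM day 63 and at 65.8 ± 7.58 CPM at SiO2 day 63.

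The direct comparison of SiO2 with BLM at day 7 asked how the models differed at the same early time. The costimulatory receptor Tnfrsf9 stood at 37.9 ± 11.9 CPM in silica and 0.581 ± 0.509 CPM in BLM, and the metalloprotease Adamdec1 at 104 ± 32.8 and 2.24 ± 0.351 CPM. Of the fibrillar collagen and cross-linking genes, 15 of 25 were higher and 2 were lower (16 and 2 adjusted over the list alone, adjusted p = 0.00441) in silica. Examples were Col1a1 (1.19 ± 0.13), Col12a1 (1.96 ± 0.20) and Loxl2 (1.15 ± 0.13) on the log2 scale. Glycolysis and hypoxia genes counted 10 of 18 higher (13 adjusted over the list alone, adjusted p = 0.00311), with Slc16a3 (3.54 ± 0.17) and Pkm (0.81 ± 0.13). Also higher in silica were Tnfrsf9 (5.95 ± 0.51), Adamdec1 (5.52 ± 0.36), the collagen Col11a1 (5.10 ± 0.64), the ectonucleotidase Nt5e (4.70 ± 0.49), the osteoclast factor Tnfsf11 (4.68 ± 0.63), and Grem1 (4.42 ± 0.33). Silica exceeded BLM in Thbs2 (3.46 ± 0.17), Postn (1.68 ± 0.26), the Wnt agonist Rspo3 (2.96 ± 0.23), the chemokines Cxcl5 (4.19 ± 0.23) and Cxcl9 (2.61 ± 0.30), and Abca1 (1.11 ± 0.14) too. Alveolar and lipid-storing fibroblast genes counted 1 of 19 higher and 12 lower (1 and 14 adjusted over the list alone, adjusted p = 0.0287), with Npnt (-1.09 ± 0.14), Limch1 (-0.87 ± 0.09) and Wnt2 (-1.99 ± 0.28). Adventitial genes counted 1 of 18 higher and 9 lower (1 and 11 adjusted over the list alone, adjusted p = 0.0415), with Cd34 (-1.16 ± 0.14) and Gsn (-1.31 ± 0.16). Mesothelial markers counted 7 of 10 lower (9 adjusted over the list alone, adjusted p = 0.0415), with Msln (-1.58 ± 0.25) and Upk3b (-2.08 ± 0.46). The p53 and senescence list counted 7 of 19 lower (8 adjusted over the list alone, adjusted p = 0.0102), with Cdkn1a (-1.14 ± 0.15), Plk2 (-0.88 ± 0.13) and Eda2r (-0.96 ± 0.17). The serpin Serpini1 (-2.90 ± 0.32), Col28a1 (-2.27 ± 0.32), the lipoxygenase Alox12 (-2.23 ± 0.30) and the MHC gene H2-Eb1 (-2.10 ± 0.27) were lower in silica. Of the 27 proliferation genes tested, 0 passed in edgeR, DESeq2 or limma-voom, and 1 had an unadjusted edgeR p under 0.05 (list test adjusted p = 0.782 with an estimated correlation). Interferon-response genes counted 2 of 26 higher (2 adjusted over the list alone, adjusted p = 0.660 with an estimated correlation). The 2 became 10 without BLM day 7 replicate 1, 4 without SiO2 day 7 replicate 1, and 1 without BLM day 7 replicate 2, BLM day 7 replicate 3 or SiO2 day 7 replicate 3. No difference passed for Timp1 (-0.08 ± 0.13), Tnc (-0.11 ± 0.17) or Top2a (0.40 ± 0.25), with adjusted p of 0.794, 0.767 and 0.381. In total 1212 genes passed, 617 higher in silica (50.9%, or 44.5% under upper quartile scaling and 49.1% under DESeq2's size factors) and 595 lower. The largest adjusted p among genes named as changed was 0.00233. Without SiO2 day 7 replicate 3 the alveolar, adventitial and mesothelial tests gave 0.0548, 0.0644 and 0.0669. The adventitial and mesothelial tests both gave 0.0588 without BLM day 7 replicate 1. The mesothelial test gave 0.0900 and 0.0512 without BLM day 7 replicate 2 or SiO2 day 7 replicate 2.

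At day 14, Spp1 held 84.4 ± 40.3 CPM in silica and 2086 ± 639 CPM in BLM, and interferon-response genes summed to 4358 ± 639 and 1469.9 ± 194 CPM. Of the interferon-response genes, 25 of 26 were higher (25 adjusted over the list alone, adjusted p = 0.0111) in silica, among them Stat2 (1.68 ± 0.18), Oasl2 (2.29 ± 0.24) and Ifit3 (2.75 ± 0.29) on the log2 scale. Complement genes counted 10 of 13 higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.0111), with C3 (1.73 ± 0.13) and C4b (1.28 ± 0.12). Chemokine and cytokine genes counted 14 of 25 higher and 1 lower (16 and 2 adjusted over the list alone, adjusted p = 0.0111), with Cxcl5 (5.24 ± 0.33), Cxcl9 (3.33 ± 0.37) and Ccl19 (2.38 ± 0.21). Adventitial genes counted 13 of 18 higher and 1 lower (15 and 2 adjusted over the list alone, adjusted p = 0.0200), with Pcolce2 (1.95 ± 0.16), Gsn (1.95 ± 0.17) and Pi16 (1.53 ± 0.18). Mesothelial markers counted 4 of 10 higher (5 adjusted over the list alone, adjusted p = 0.330 with an estimated correlation). Dissociation and immediate-early genes counted 10 of 20 higher and 1 lower (12 and 2 adjusted over the list alone, adjusted p = 0.284 with an estimated correlation). Also higher in silica were Tnfrsf9 (3.55 ± 0.55), the vanin Vnn3 (3.38 ± 0.53), the channel Cngb3 (3.72 ± 0.58), Inmt (1.78 ± 0.24), Npnt (1.03 ± 0.14), and the heat shock pair Hspa1a (1.53 ± 0.23) and Hspa1b (1.65 ± 0.24), whose near-identical sequences share tags. Matrix glycoprotein and proteoglycan genes counted 4 of 23 higher and 12 lower (4 and 14 adjusted over the list alone, adjusted p = 0.0111), with Spp1 (-4.63 ± 0.34), Fn1 (-1.89 ± 0.16) and Cthrc1 (-3.72 ± 0.28) lower in silica. Contractile genes counted 1 of 20 higher and 15 lower (1 and 15 adjusted over the list alone, adjusted p = 0.0461), with Actg2 (-2.25 ± 0.24), Acta2 (-1.25 ± 0.21) and Tpm2 (-1.45 ± 0.15) lower. Proliferation genes counted 18 of 27 lower (23 adjusted over the list alone, adjusted p = 0.0461), with Mki67 (-2.27 ± 0.39) and Top2a (-1.71 ± 0.31). Thrombospondin Thbs4 (-5.84 ± 0.44), the fibrillin Fbn2 (-5.72 ± 0.46), the collagens Col8a1 (-5.69 ± 0.56) and Col1a1 (-0.64 ± 0.13), Lrrc15 (-4.62 ± 0.37) and Adam12 (-2.89 ± 0.29) were lower in silica. Myeloid markers counted 4 of 8 higher (7 adjusted over the list alone, adjusted p = 0.0532 with an estimated correlation), with Mpeg1 (2.43 ± 0.41) and Tyrobp (1.09 ± 0.26) higher. In total 1994 genes passed, 1057 higher in silica and 937 lower. Among genes named as changed the largest adjusted p was 0.00296. The contractile and proliferation tests gave 0.0522 and 0.0520 without BLM day 14 replicate 1, and both gave 0.0657 and 0.0692 without SiO2 day 14 replicate 2 or 3.

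At day 63, the late comparison of the progressive with the reversible model, Saa3 stood at 781 ± 50.4 CPM in silica against 13.0 ± 6.77 CPM in BLM, and Timp1 at 75.5 ± 11.9 against 17.9 ± 3.79 CPM. Of the chemokine and cytokine genes, 19 of 25 were higher and 1 was lower (21 and 2 adjusted over the list alone, adjusted p = 0.000569) in silica. Those higher included Cxcl5 (6.12 ± 0.34), Saa3 (5.94 ± 0.43), Ccl19 (3.16 ± 0.20) and Cxcl12 (1.96 ± 0.15) on the log2 scale. Matrix glycoprotein and proteoglycan genes counted 15 of 23 higher and 3 lower (15 and 3 adjusted over the list alone, adjusted p = 0.00818), with Postn (4.32 ± 0.32), Spp1 (4.24 ± 0.40), Thbs2 (2.67 ± 0.17) and Sparc (1.09 ± 0.09). Fibrillar collagen and cross-linking genes counted 15 of 25 higher and 1 lower (15 and 1 adjusted over the list alone, adjusted p = 0.0106), with Col1a1 (1.12 ± 0.13), Col3a1 (1.15 ± 0.12) and Col5a2 (1.37 ± 0.15). Basement membrane genes counted 7 of 16 higher and 1 lower (7 and 2 adjusted over the list alone, adjusted p = 0.0318), with Col4a2 (1.38 ± 0.10). The protease inhibitor Timp1 (2.09 ± 0.16) and the contractile genes Acta2 (1.91 ± 0.23) and Actg2 (2.48 ± 0.31) were higher, and the collagenase Mmp13 was at least 26.9-fold higher. Complement genes counted 8 of 13 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.0323), with C3 (1.89 ± 0.13) and Cfb (1.29 ± 0.18). Interferon-response genes counted 22 of 26 higher and 1 lower (22 and 1 adjusted over the list alone, adjusted p = 0.0512 with an estimated correlation), with Zbp1 (2.31 ± 0.31) and Psmb8 (1.15 ± 0.12). LXR targets counted 4 of 14 higher (5 adjusted over the list alone, adjusted p = 0.0323), with Pltp (2.02 ± 0.21), Rgs16 (1.93 ± 0.24) and Abca1 (0.95 ± 0.14). Proliferation genes counted 8 of 27 higher (8 adjusted over the list alone, adjusted p = 0.339 with an estimated correlation), with Top2a (2.69 ± 0.47), and their median log2 difference was 1.15, or 1.10 with members at 0 counts set to their bound. The iron-binding lipocalin Lcn2 (5.43 ± 0.33) was higher. Alveolar and lipid-storing fibroblast genes counted 1 of 19 higher and 12 lower (2 and 13 adjusted over the list alone, adjusted p = 0.0512 with an estimated correlation), with Inmt (-1.78 ± 0.23) and Itga8 (-0.82 ± 0.11). The adhesion molecules Alcam (-2.05 ± 0.18), Lsamp (-1.98 ± 0.26) and Fat3 (-1.99 ± 0.31), the angiotensin receptor Agtr1b (-1.94 ± 0.23), Rab6b (-1.97 ± 0.42) and Cdkn1a (-1.13 ± 0.15) were lower in silica. Myeloid markers counted 5 of 8 higher (6 adjusted over the list alone, adjusted p = 0.0323), with Tyrobp (2.50 ± 0.31) at 18.1 ± 2.51 CPM against 3.23 ± 1.13 CPM. Lymphocyte markers counted 2 of 3 higher (2 adjusted over the list alone, adjusted p = 0.0106), with Cd3e and Cd4 at 0 CPM in silica. In total 1816 genes passed, 1065 higher in silica (58.6%, or 50.6% under upper quartile scaling) and 751 lower. The largest adjusted p among genes named as changed was 0.00114. The LXR test gave 0.0562 without SiO2 day 63 replicate 1. The myeloid test gave 0.0518 without BLM day 63 replicate 3, and the lymphocyte test 0.258 with no filter.

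Within the reversible model, BLM day 63 was compared with day 14 to follow resolution. Spp1 went from 2086 ± 639 to 8.95 ± 4.61 CPM, and Inmt from 141 ± 35.0 to 1323 ± 46.2 CPM, with 1285 ± 64.0 CPM in untreated lungs. Of the matrix glycoprotein and proteoglycan genes, 4 of 23 rose and 16 fell (4 and 16 adjusted over the list alone, adjusted p = 0.000581). Members Spp1 (-7.90 ± 0.42), Cthrc1 (-5.69 ± 0.35), Postn (-4.74 ± 0.32) and Fn1 (-2.72 ± 0.16) fell on the log2 scale. Fibrillar collagen and cross-linking genes counted 2 of 25 higher and 18 lower (2 and 18 adjusted over the list alone, adjusted p = 0.00226), with Col1a1 (-2.66 ± 0.14), Col5a1 (-2.35 ± 0.13) and Lox (-2.27 ± 0.16). Basement membrane genes counted 3 of 16 higher and 9 lower (5 and 9 adjusted over the list alone, adjusted p = 0.0147), with Col4a1 (-2.53 ± 0.16). Matrix proteases and inhibitors counted 3 of 21 higher and 12 lower (3 and 13 adjusted over the list alone, adjusted p = 0.0147), with Timp1 (-2.96 ± 0.16), Adam12 (-5.66 ± 0.40) and Adamts12 (-2.83 ± 0.22). Proliferation genes counted 26 of 27 lower (26 adjusted over the list alone, adjusted p = 0.0433), with Mki67 (-5.00 ± 0.55) and Top2a (-4.44 ± 0.42). Contractile genes counted 1 of 20 higher and 15 lower (2 and 15 adjusted over the list alone, adjusted p = 0.0969 with an estimated correlation), with Actg2 (-4.38 ± 0.29) and Acta2 (-2.42 ± 0.22). The fibrillin Fbn2 was 247-fold lower (95% counting interval 43.9 to 9820.3) and the chemokine Cxcl13 93.1-fold lower (95% counting interval 31.5 to 455). Alveolar and lipid-storing fibroblast genes counted 13 of 19 higher and 3 lower (15 and 3 adjusted over the list alone, adjusted p = 0.0969 with an estimated correlation), with Inmt (3.22 ± 0.25), Scn3a (2.57 ± 0.20), G0s2 (2.27 ± 0.20) and Itga8 (1.30 ± 0.11) among those that rose. Dissociation and immediate-early genes counted 13 of 20 higher and 1 lower (13 and 1 adjusted over the list alone, adjusted p = 0.239 with an estimated correlation), with Egr1 (0.98 ± 0.12), Nr4a1 (0.97 ± 0.14) and Atf3 (1.20 ± 0.18). Periplakin Ppl (3.39 ± 0.46), the cytochrome Cyp2e1 (3.07 ± 0.22), Tppp (3.04 ± 0.18) and Cbfa2t3 (2.99 ± 0.32) rose. The noncoding RNA Snhg11 (4.35 ± 0.40) and the adventitial genes Gsn (2.74 ± 0.17) and Pcolce2 (2.53 ± 0.16) rose too. In total 3768 genes passed, 1796 higher at day 63 (47.7%, or 53.4% under upper quartile scaling) and 1972 lower. Among genes named as changed the largest adjusted p was 3.54e-06. The proliferation test gave 0.0627 and 0.0742 without BLM day 63 replicate 1 or 3.

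Within the progressive model, SiO2 day 63 was compared with day 14. Mesothelial markers summed to 258 ± 19.1 CPM at day 63 and 489 ± 74.2 CPM at day 14, of which Upk1b made 194 ± 19.1 and 302 ± 26.2 CPM. Of these markers, 7 of 10 fell (8 adjusted over the list alone, adjusted p = 0.0122). Those lower included Msln (-1.45 ± 0.24), Aldh1a2 (-1.58 ± 0.26), Krt19 (-1.65 ± 0.28) and Upk1b (-0.63 ± 0.12) on the log2 scale. Adventitial genes counted 7 of 18 lower (14 adjusted over the list alone, adjusted p = 0.0122), with Pi16 (-1.56 ± 0.18), Cd248 (-1.67 ± 0.23) and Clec3b (-1.35 ± 0.20). Basement membrane genes counted 4 of 16 lower (5 adjusted over the list alone, adjusted p = 0.0122), with Npnt (-0.93 ± 0.13) and Nid1 (-0.60 ± 0.11). The chemokine Cxcl13 (-2.43 ± 0.33), Wfdc10 (-3.64 ± 0.62), the endocytic receptor Lrp2 (-2.41 ± 0.40) and Fxyd3 (-2.23 ± 0.35) fell. So did the notch target Hey2 (-1.99 ± 0.29), Col1a1 (-0.90 ± 0.13), Eln (-0.76 ± 0.16) and complement Cfb (-0.99 ± 0.15). Higher at day 63 were the cartilage protein Cilp (2.11 ± 0.30), Ankrd1 (2.09 ± 0.32), a gene of mechanical load, Snhg11 (2.64 ± 0.26) and Ccl19 (0.88 ± 0.17). Periostin Postn (1.08 ± 0.24) was also higher, a call that ended without SiO2 day 14 replicate 3 (0.75, adjusted p = 0.0653). Changes did not pass for Col3a1 (-0.09 ± 0.12), Fn1 (-0.16 ± 0.15), Tnc (0.13 ± 0.18), Timp1 (-0.11 ± 0.14), Inmt (-0.34 ± 0.23) or Abca1 (0.03 ± 0.14), with adjusted p of 0.788, 0.687, 0.796, 0.783, 0.503 and 0.949. Interferon-response genes counted 3 of 26 lower (14 adjusted over the list alone, adjusted p = 0.303 with an estimated correlation). Epithelial markers counted 0 of 5 higher and 1 lower (1 and 3 adjusted over the list alone, adjusted p = 0.0889 with an estimated correlation) with a median log2 change of -0.92, and myeloid markers counted 1 of 8 lower (3 adjusted over the list alone, adjusted p = 0.254 with an estimated correlation) with a median of -0.73. Of the 27 proliferation genes tested, 0 passed in edgeR, DESeq2 or limma-voom, and 3 had an unadjusted edgeR p under 0.05 (list test adjusted p = 0.890 with an estimated correlation). In total 411 genes passed, 178 higher at day 63 and 233 lower. The largest adjusted p among genes named as changed was 0.00748. The total was 201, 231, 249 and 265 without SiO2 day 63 replicate 2, SiO2 day 14 replicate 3, SiO2 day 63 replicate 3 and SiO2 day 63 replicate 1.

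The interaction of model and time asked whether the change from day 14 to day 63 differed between the models. Values above 0 mark a change that was more positive in silica. Lrat, which stores vitamin A as esters, went from 41.2 ± 10.3 to 314 ± 87.6 CPM in BLM and from 203 ± 102 to 122 ± 22.2 CPM in silica. Of the matrix glycoprotein and proteoglycan genes, 15 of 23 were positive and 3 were negative (15 and 3 adjusted over the list alone, adjusted p = 0.00108). Among the positive were Spp1 (8.87 ± 0.52), Postn (5.81 ± 0.40), Cthrc1 (5.86 ± 0.55) and Fn1 (2.56 ± 0.22) on the log2 scale. Fibrillar collagen and cross-linking genes counted 15 of 25 positive and 2 negative (16 and 3 adjusted over the list alone, adjusted p = 0.0142), with Col1a1 (1.75 ± 0.19), Col5a2 (2.35 ± 0.21) and Lox (1.79 ± 0.21). Matrix proteases and inhibitors counted 9 of 21 positive and 1 negative (10 and 3 adjusted over the list alone, adjusted p = 0.0327), with Timp1 (2.86 ± 0.21). Contractile genes counted 13 of 20 positive and 0 negative (15 and 1 adjusted over the list alone, adjusted p = 0.0586 with an estimated correlation), with Actg2 (4.74 ± 0.39), Acta2 (3.16 ± 0.31) and Tagln (2.48 ± 0.34). Proliferation genes counted 15 of 27 positive (18 adjusted over the list alone, adjusted p = 0.0922 with an estimated correlation), with Top2a (4.40 ± 0.56) and Mki67 (4.78 ± 0.83). The fibrillin Fbn2 (8.73 ± 1.13), thrombospondin Thbs4 (6.64 ± 0.70) and the chemokine Cxcl12 (2.23 ± 0.20) were positive too. Alveolar and lipid-storing fibroblast genes counted 1 of 19 positive and 15 negative (1 and 16 adjusted over the list alone, adjusted p = 0.0344), with Inmt (-3.57 ± 0.34), Scn3a (-3.00 ± 0.28), Npnt (-2.04 ± 0.19) and Itga8 (-1.43 ± 0.15) negative. Adventitial genes counted 1 of 18 positive and 11 negative (2 and 11 adjusted over the list alone, adjusted p = 0.0512 with an estimated correlation), with Gsn (-3.17 ± 0.23) and Pcolce2 (-3.22 ± 0.22). Dissociation and immediate-early genes counted 1 of 20 positive and 12 negative (1 and 16 adjusted over the list alone, adjusted p = 0.176 with an estimated correlation), with Egr1 (-1.09 ± 0.16), Nr4a1 (-1.29 ± 0.19) and Atf3 (-1.61 ± 0.25). The genes Lrat (-3.66 ± 0.41), Slc7a10 (-4.47 ± 0.82), Fxyd3 (-4.01 ± 0.56), Ppl (-3.82 ± 0.60), Lsamp (-3.66 ± 0.37) and the microtubule gene Mapt (-3.61 ± 0.49) were negative. No difference passed for Srebf1 (-0.09 ± 0.31) or Abca1 (0.21 ± 0.20), with adjusted p of 0.888 and 0.535. In total 2160 genes passed, 1132 positive (52.4%, or 47.5% under upper quartile scaling) and 1028 negative. Among genes named as changed the largest adjusted p was 0.000139. Without BLM day 14 replicate 1, the protease and alveolar tests gave 0.0505.

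**Figure D4:**
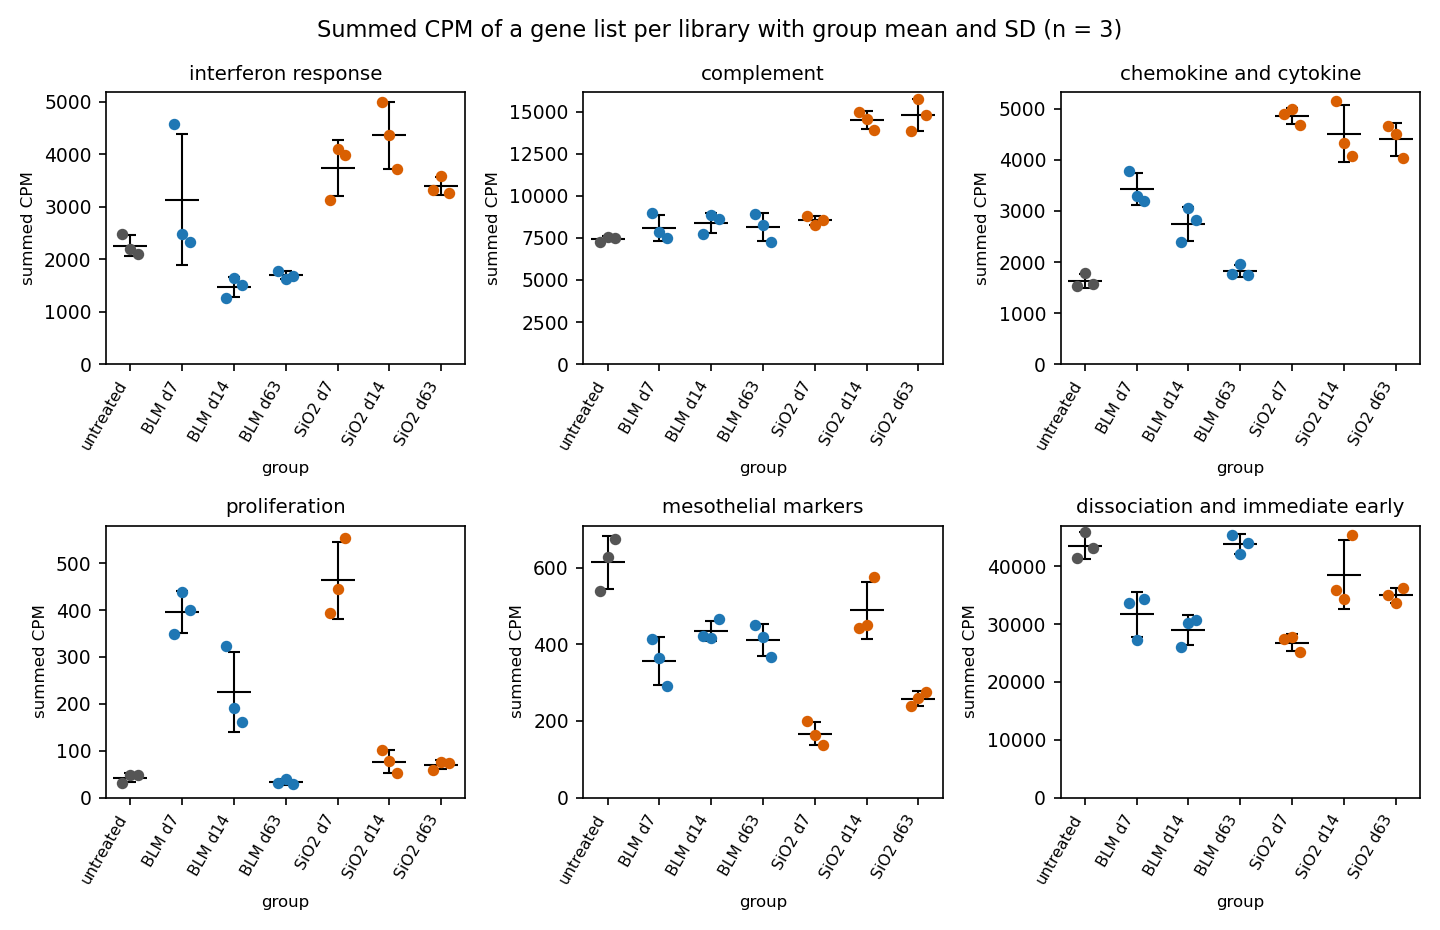
Summed expression in CPM of 6 gene lists (interferon response, complement, chemokine and cytokine, proliferation, mesothelial, immediate early) in each of the 21 libraries by group, with points for libraries and a bar for the mean and SD of 3 libraries. Interferon-response genes summed to 1469.9 ± 194 CPM at BLM day 14 and 4358 ± 639 CPM at SiO2 day 14.

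The genes that passed against untreated mice at day 7 or 14 were followed to day 63 within each model. In the reversible model 978 of 5333 early genes (18.3%) passed again at day 63 in the same direction, 510 of 2809 that had risen and 468 of 2524 that had fallen. In the progressive model 2724 of 5619 (48.5%) did, 1494 of 3039 that had risen and 1230 of 2580 that had fallen. Tenascin Tnc stayed higher in both models, with log2 fold changes at day 63 of 1.91 ± 0.22 in BLM and 2.67 ± 0.21 in silica. In the opposite direction, 91 early genes passed at BLM day 63 and 37 at SiO2 day 63. By sign alone, 4045 early genes of the reversible and 5085 of the progressive model kept their direction. Since early and late comparisons shared the untreated libraries, part of that may come from the shared controls. The difference between these shares had no test of its own, and the interaction above covered day 14 to day 63 only. The reversible share was 11.5% without BLM day 63 replicate 3, against 18.3% with all libraries.

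The changes of both models against the same untreated libraries were set side by side. Across the 11669 tested genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.876 at day 7, 0.769 at day 14 and 0.612 at day 63, and Spearman's rho was 0.841, 0.738 and 0.606. Unchanged groups simulated 20 times against the same controls gave a mean r of 0.519, 0.512 and 0.533, with 0 genes that passed in both comparisons. The covariance was 0.898, 0.632 and 0.312 against a simulated 0.0505, 0.0511 and 0.0505, a difference of 0.848, 0.580 and 0.262. At day 7, 1661 genes rose and 1479 fell in both models, where independent lists would share 457 and 358. At day 14, 1158 rose and 1023 fell in both (328 and 227 for independent lists), and at day 63, 529 rose and 448 fell (108 and 80.1). Genes that passed in opposite directions numbered 9, 50 and 35. The 3 untreated libraries could not be split with 2 on each side, so part of the excess may come from the shared controls.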

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

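All tests of explanations given here, except the pair on scaling between libraries, were chosen after the result was seen.

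The fibroblasts of the silica and BLM models differed from each other at each day when compared directly. At day 7, 1212 genes passed, at day 14, 1994, at day 63, 1816, and the change from day 14 to day 63 differed between the models for 2160. These results stand out because a test set the models against each other. Spp1 showed the turn, as it was lower in silica at day 14 (-4.63 ± 0.34) and higher at day 63 (4.24 ± 0.40), with an interaction of 8.87 ± 0.52 on the log2 scale. Against untreated mice, 9 genes passed in opposite directions in the models at day 7, 50 at day 14 and 35 at day 63, counts with no test of their own.

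At day 7, silica exceeded BLM in the lists of glycolysis and hypoxia (adjusted p = 0.00311), fibrillar collagen and cross-linking (0.00441) and pericyte and smooth muscle markers (0.0125). It was below BLM in p53 and senescence (0.0102), alveolar and lipid-storing fibroblast (0.0287), adventitial fibroblast and mesothelial genes (both 0.0415), by camera with an estimated correlation. Without SiO2 day 7 replicate 3, the alveolar, adventitial and mesothelial tests gave 0.0548, 0.0644 and 0.0669. Without BLM day 7 replicate 1 the adventitial and mesothelial tests gave 0.0588, and the mesothelial test gave 0.0900 without BLM day 7 replicate 2 and 0.0512 without SiO2 day 7 replicate 2.

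At day 14, silica exceeded BLM in interferon response, complement and chemokine and cytokine genes and fell short in matrix glycoprotein and proteoglycan genes (each adjusted p = 0.0111). It exceeded BLM in adventitial genes (0.0200) and fell short in contractile and proliferation genes (both 0.0461). The last pair gave 0.0522 and 0.0520 without BLM day 14 replicate 1, and both gave 0.0657 and 0.0692 without SiO2 day 14 replicate 2 or 3. At day 63, silica exceeded BLM in chemokine and cytokine (0.000569), matrix glycoprotein and proteoglycan (0.00818), fibrillar collagen and cross-linking and lymphocyte (both 0.0106), basement membrane and pericyte (both 0.0318), and LXR target, complement and myeloid genes (each 0.0323). With no filter on low counts the lymphocyte and pericyte tests at day 63 gave 0.258 and 0.114, and the LXR and myeloid tests gave 0.0562 without SiO2 day 63 replicate 1 and 0.0518 without BLM day 63 replicate 3. In the interaction, matrix glycoprotein and proteoglycan (0.00108), fibrillar collagen and cross-linking (0.0142) and matrix protease and inhibitor genes (0.0327) were positive and alveolar genes (0.0344) negative, and the last pair gave 0.0505 without BLM day 14 replicate 1.

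Regrouping the libraries gave fewer calls. For the interaction, 100 of the 200 splits were drawn, and 1, the real one with 2160 genes, called as many. Splits that broke up a group mixed libraries of models that differ, which widens the spread and lowers the count (at most 765), so their share does not test the interaction. Of the 2 splits with unbroken groups, too few for a share under 0.05, the other exchanged the models at day 63 and called 1223 genes. For the other 11 comparisons the 6 libraries make 10 splits, too few for a share under 0.05. The other splits mix the 2 groups, which widens the spread, so their low counts do not test the calls. They called at most 6 genes for SiO2 against BLM at day 7, 1 at day 63 and 0 in every other comparison. The real splits called 411 to 5142.

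Interferon-response genes such as Stat2 differed between the models at day 14, with 25 of 26 members higher in silica, and their summed expression differed from untreated by 872 (153 without BLM day 7 replicate 1), -786 and -559.5 CPM at BLM day 7, 14 and 63 and by 1481, 2102 and 1128 CPM at SiO2 day 7, 14 and 63. A loss of leukocyte RNA is argued against at BLM day 14 by a myeloid marker sum 4.89 CPM above untreated (pooled SD 11.1, with -1.78 and 11.0 CPM without untreated replicate 1 and 3 and 8.73 and -0.0311 CPM without BLM day 14 replicate 1 and 2). At BLM day 63 that sum differed by -14.5 CPM (pooled SD 9.67, -8.41 without untreated replicate 3), and the interferon fall was 38.5 times as large. A gain of myeloid RNA at SiO2 day 7 is argued against by a myeloid sum 6.36 CPM above untreated (pooled SD 9.63, with -0.311 and 12.5 CPM without untreated replicate 1 and 3 and 3.84 CPM without SiO2 day 7 replicate 2) beside an interferon rise of 1481 CPM. At SiO2 day 14 and 63 the myeloid sum was 58.9 CPM (pooled SD 13.8) and 28.2 CPM (pooled SD 10.4) above untreated while the interferon sum rose at least 35.7 times as much, which argues against myeloid cells that escaped the CD45 depletion as the source of the whole rise, since such cells would bring their own abundant transcripts. Scaling between libraries is argued against, since at least 25 of the 26 members were called higher in silica than BLM at day 14 under DESeq2's size factors and upper quartile factors, and a difference in interferon signalling between the models is an open explanation with no test of its own.

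Mesothelial and adventitial markers such as Msln and Pi16 were lower in silica at day 63 than at day 14 (both list tests adjusted p = 0.0122). A higher fibroblast share at day 63 would lower markers of every other cell type. The epithelial and myeloid medians fell (-0.92 and -0.73), while the pericyte median lay 1.78 above the mesothelial (SE 0.393, log2). Fibroblasts may express pericyte genes such as Actg2, so a higher share stays open. Fewer mesothelial cells among the sorted cells would lower the mesothelial members by a common amount. Their changes were uneven (Cochran's chi-square test over genes with the SE derived from edgeR's F, p = 7.44e-05, common log2 change -1.08). Without Upk1b the others were even (same chi-square test, p = 0.366, common change -1.44), so fewer mesothelial cells, which no depletion antibody targeted, may explain part of the mesothelial fall and stay open. The adventitial changes were uneven too (same chi-square test, p = 1.14e-18, common change -0.57), and whether the silica model itself lowered the genes of either list in fibroblasts was not tested.

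Immediate-early genes such as Egr1 and Atf3 were lower than untreated early, with 14 of 20 members called lower at SiO2 day 7, and at least 14 stayed lower there under DESeq2's size factors and upper quartile factors, which argues against scaling between libraries. Handling of the tissue before lysis could lower such genes, and then heat shock genes would tend to fall with them. Of 9 heat shock values at BLM day 7, BLM day 14 and SiO2 day 7, 0 were called lower in edgeR, which decides nothing for the other immediate-early genes. The 2 called higher, the near-identical Hspa1a (0.66) and Hspa1b (0.65) at SiO2 day 7, ended in DESeq2 (adjusted p = 0.0915 and 0.109) and without untreated replicate 1 (0.57 and 0.57), untreated replicate 2 (0.61 and 0.58) or SiO2 day 7 replicate 2 (0.27 and 0.26). Handling and an effect of the models on these genes therefore cannot be told apart.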

How the results depend on the processing

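The alternatives were fixed before the data were examined, and none was chosen after a result was seen. Counts of called genes stayed within 1.5 times of those reported under DESeq2's size factors, upper quartile factors, no filter, the CPM filter, DESeq2, limma-voom and a fit on the compared groups alone, and no scaling moved the median of all genes by over 0.1. With a minimum of 2-fold, which removes small changes by construction, the counts were 1472, 2015 and 366 for BLM against untreated at day 7, 14 and 63, and 2421, 1029 and 1315 for SiO2. They were 460, 816 and 698 for SiO2 against BLM, 1485 and 160 for day 63 against day 14 in BLM and SiO2, and 1234 for the interaction, and the share of early genes called again at day 63 was 10.6% in BLM and 40.2% in SiO2. Without a filter the SiO2 share was 45.9%, and with the CPM filter the correlation between models was 0.887 at day 7 and 0.638 at day 63, for which the cause was not tested. Of the 324 list tests, 170 passed with a preset correlation and 205 with fry, which does not compare a list with other genes, against 64 reported. With no filter, 4 of these 64 list calls ended: pericyte and smooth muscle markers at SiO2 day 7 (0.0520), at SiO2 day 14 (0.0772) and at SiO2 against BLM at day 63 (0.114), and lymphocyte markers at SiO2 against BLM at day 63 (0.258).

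With 1 library left out, which lowers the number of samples, gene counts for BLM against untreated ran from 2892 to 3488 (day 7), 3878 to 4269 (day 14) and 795 to 1219 (day 63). The day 63 count was lowest without untreated replicate 1 and was 814 without BLM day 63 replicate 3. Counts for SiO2 against untreated ran from 4423 to 4892, 2023 to 2873 and 2629 to 2938, and for SiO2 against BLM from 842 to 1133, 1372 to 1772 and 1354 to 1502. Counts ran from 1775 to 2093 for the interaction and from 3006 to 3328 for BLM day 63 against day 14. For SiO2 day 63 against day 14 the count was 201 without SiO2 day 63 replicate 2, 231 without SiO2 day 14 replicate 3, 249 without SiO2 day 63 replicate 3, 265 without SiO2 day 63 replicate 1, and at most 325. The early share ran from 11.5% (without BLM day 63 replicate 3) to 19.8% in BLM and from 41.6% to 52.6% in SiO2, and the correlation from 0.876 to 0.884, 0.772 to 0.793 and 0.628 to 0.655 at day 7, 14 and 63. List tests that passed numbered 55 to 79. Of the 64 list calls, 17 ended without 1 library. Genes that lost their call this way were mostly passed over when the named genes were picked, so 8 values of 2640 that turned weaker describe the picked genes only. These were Postn and Chn2 at SiO2 day 63 against day 14 and Hspa1a and Hspa1b at SiO2 day 7, and none reversed. The last pair also lost their calls in DESeq2 (adjusted p = 0.0915 and 0.109).

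The replicate numbers did not pair the libraries. Deviations from the group means correlated with a mean of -0.005 over 63 pairs with the same number, 0 pairs were over 0.1, and 5 of 21 libraries correlated best with their own number. With the number as a replicate block, the counts of called genes were within 1.5 times of those reported (3624 for BLM day 7, 1281 for BLM day 63 and 387 for SiO2 day 63 against day 14), and no call of a named gene was lost. With it 57 list tests passed, and the 7 calls that ended were proliferation at SiO2 day 7 (0.0629) and at BLM day 63 against day 14 (0.0648), alveolar and lipid-storing fibroblast genes at SiO2 day 63 (0.0523), adventitial and mesothelial genes at SiO2 against BLM at day 7 (both 0.0612), and contractile and proliferation genes at SiO2 against BLM at day 14 (both 0.0646). In simulated data for BLM day 7 against untreated, 26.6% of the genes changed 1.5-fold were recovered, so small changes can be missed.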

Other observations

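The tests here were chosen after the result was seen, except the comparison of SiO2 day 63 with the BLM profiles.

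Some genes were called against untreated only at day 63. With 1 untreated group, age at day 63 cannot be told apart from a late effect of the models. In silica, 42 genes with at least 10 CPM in some group passed at day 63 against untreated and against day 14 in the same direction but at neither earlier day, 20 higher and 22 lower. Among them were the cartilage intermediate layer protein Cilp (3.03 ± 0.34), the chemokine Cx3cl1 (2.96 ± 0.40) and Ankrd1 (2.44 ± 0.34), as log2 fold changes at day 63 ± SE. A missing call is not a missing change, as Cilp and Cx3cl1 stood at 0.92 and 0.99 at day 14 without passing. In BLM, 154 genes did so, 80 higher and 74 lower, with Clip4 (1.23 ± 0.19) and Pamr1 (1.12 ± 0.15) higher and the transcription factor Creb3l1 (-1.07 ± 0.19) lower. Chn2, which acts on a small GTPase, was late and lower in both models, at -1.14 ± 0.25 in BLM and -1.56 ± 0.26 in silica, and its fall in silica from day 14 ended without SiO2 day 14 replicate 3 (-0.98, adjusted p = 0.0549). These genes fall outside the rule for named genes and were chosen after their values were seen.

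LXR target genes such as Abca1 and Pltp were higher in silica at day 14 and 63, which led to the hypothesis that the fibroblasts were loaded with sterol. Sterol loading represses cholesterol synthesis genes. Of 24 such genes, 7 were called higher than untreated and 1 lower at SiO2 day 14 and 9 higher and 1 lower at day 63, differences of 6 and 8 towards higher, which argues against sterol loading as the source of the LXR pattern at both days. Srebf1, which is both an LXR target and a regulator of lipid synthesis, did not pass in any of the 12 comparisons by edgeR's quasi-likelihood test.

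A further hypothesis was that silica at day 63 holds the BLM day 14 profile more than the BLM day 63 profile. Across genes, which are not independent replicates, the log2 changes against untreated at SiO2 day 63 correlated with those at BLM day 14 at 0.746 and with those at BLM day 63 at 0.612, a difference of 0.134 (0.115 to 0.198 with any 1 library left out). The changes had an SD of 1.05 at BLM day 14 and 0.58 at BLM day 63, and a smaller profile correlates less under the same noise whatever silica holds. Shared untreated libraries also raise both correlations, so these values leave the hypothesis undecided.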
